A study of Mus musculus with 384 samples.

How the data were processed

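The data were single-cell FACS-seq profiles of mouse kidney from animals aged 8 weeks, per the labels. In FACS-seq, single cells are sorted into the wells of a plate and each well becomes 1 library with its own barcode. Wells of 2 sort gates were analysed, cells positive for PDGFRB and negative for CD45 (here CD45-) and cells positive for both (CD45+), each in 2 batches, which gave 4 plates of 96 wells and 384 wells in all. The well names carry the abbreviation UUO, which the labels do not spell out. Each well is listed as 1 sample and no animal, donor or culture is named, so each plate was treated as 1 sample and no p-value or standard error was computed from cells.

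The deposited values were raw read counts per gene and well, per the labels and from the values, which were whole numbers with a different total in each well. Complementary DNA was made in each well with a Clontech SMARTer kit and plates were pooled for paired sequencing, per the labels' protocols. Per the submitters' processing notes, STAR (listed as version 3.0.4), Subread and featureCounts 1.4.5 were used; which step each did, the genome build and the annotation release were not given in the sources used here. Molecular identifiers were not stated, so read counts were not taken as counts of molecules. The deposited tables listed some Ensembl genes more than once with identical counts. These 598 repeated lines of batch 1 (of 41192) and 595 of batch 2 (of 41228), which held 2.39% and 2.42% of the summed counts, were dropped, and the 40594 genes present in both tables were used. Names were taken from the deposited tables, and 40254 of the gene identifiers were also found in a reference name table. Where a symbol belonged to several identifiers, it was given to the one with the most reads.

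A well was kept as a cell with at least 10000 reads on genes and at least 500 genes with a read, which kept 368 wells and left out 16. The wells left out held 5323 to 9740 reads each, 0.106% of the 116166837 reads. Levels are CPM, reads scaled to the same total for each plate, of the reads summed over a plate's kept cells. Gates were compared within each batch as the log2 ratio of CPM plus a pseudocount of 1, CD45+ over CD45-. This scale understates the ratio of genes near 0 in 1 gate. A gene was called higher in a gate only where both batches differed at least 4-fold in the same direction. A list's median log2 ratio was placed among 10000 random lists of the same size, matched on mean level in 20 bins, over genes of at least 1 CPM on average. That percentile describes these plates and is not a test. For shares of cells with a read, each kept cell was thinned at random to 50000 reads, the largest of a preset series of depths that at least 80% of kept cells reached in each plate. This used 79 and 82 CD45- cells and 76 and 78 CD45+ cells of batches 1 and 2. Shares have exact Clopper-Pearson 95% intervals and CPM values exact Poisson 95% intervals, both of which cover counting error only, and a share of 0 is given with its exact upper bound.

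Kept cells of all plates were clustered with scanpy 1.11.5 and leidenalg 0.10.2: scaling to 10000 counts per cell, log transform, 2000 variable genes, 20 principal components, 15 neighbours and Leiden resolution 1. A class name was given only to a cluster with at least 3 detected markers of that class (at least 100 CPM in 25% of its cells and a log2 ratio to the other cells of at least 1), and only where no other class had more markers among the 10 leading genes. Shallow clusters with none of their markers among those 10 stayed unnamed. No doublet caller was run, because single cells were sorted into wells, which does not exclude wells with more than 1 cell. More than 1 cell was weighed only for the well with most collagen reads. No caller of free RNA was run either, and wells under 50000 reads served as a measure of reads carried between wells.

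The gates, filters, thinning, gene lists, markers, clustering settings, the rule for named genes and most alternatives were fixed before the data were examined. The level of 100 CPM, also used in naming clusters, the limit of 50000 reads for near-empty wells, the exclusion of 1 collagen-rich well and the leaving out of each well in turn were chosen afterwards. Where 1 well moved a printed ratio or level of a called gene or a list median by over 1.5 times, or changed a call, the value without it is given where that value is first described. Named genes were the 12 per gate with the largest smaller log2 ratio of both batches, among genes of at least 20 CPM in 1 gate in both batches and with a read in at least 10% of that gate's cells, without mitochondrial, ribosomal protein, pseudogene and predicted genes. The 4 most abundant members of each list and Pdgfrb, Ptprc, Col1a1, Col1a2, Col3a1, Acta2 and Postn were also named, as were up to 5 leading genes per cluster. Some genes that these rules name are not reported here. Other genes named in the text are members of these lists or were chosen after their values were seen, as stated there. The 11 lists were matrix, matrix remodelling, contractile, TGF-beta signalling, PDGF and hedgehog signalling, antigen presentation, chemokines and receptors, complement, interferon response, dissociation and stress, and fibrocyte-associated genes. The 18 marker lists were fibroblast, pericyte, smooth muscle, mesangial, leukocyte, monocyte, macrophage, dendritic, neutrophil, T cell, NK cell, B cell, endothelial, proximal tubule, distal tubule and collecting duct, podocyte, erythroid and proliferating cell markers.

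The gate comparison was tested on simulated data drawn from the real library sizes, with all 40594 genes. Of 100 genes changed 8-fold and 100 changed 16-fold, all of 20 to 200 CPM before the change, 100% of each were recovered, and 0 of 40394 unchanged genes were called. Unchanged genes near 0 CPM could hardly be called with a pseudocount of 1. Among the 5190 unchanged genes of at least 20 CPM, 0 were called. The simulated changes were well above the 4-fold limit. The simulated plates shared 1 profile apart from the changed genes, with random spread between wells. They had no batch difference, no reads carried between wells and no well made to hold most of a gene's reads. In the real plates, 507 genes differed 4-fold in opposite directions, so these figures do not give the rate of false calls there. In simulated cells of 2 profiles, the summed reads of each gate, 100% of 368 cells fell in clusters that held only their own profile. This figure does not fall when a profile is split over several clusters. These cells also had no batch difference and no carried reads, so the names of clusters were not tested. Alternatives were the mean over cells in place of summed reads, TMM factors (edgeR 4.0.16 in R 4.3.3), totals without mitochondrial genes, a pseudocount of 5, other cell and gene filters, each batch alone, other read thresholds, and other clustering settings. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.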

Results

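Single PDGFRB+ cells of mouse kidney were profiled from 2 sort gates, CD45- and CD45+, in 2 batches. PDGFRB is a growth factor receptor of pericytes and fibroblasts, and CD45, encoded by Ptprc, is a phosphatase on the surface of leukocytes. The series title asks how far monocytes add to the myofibroblasts, the contractile, matrix-making cells of the fibrotic kidney, and the comparison of the gates addresses which cells held matrix and contractile transcripts. In batch 1, 93 CD45- and 92 CD45+ cells were kept of 96 wells each, and in batch 2, 93 and 90. The wells held 5323 to 1246070 reads on genes. Summed reads of all wells were 29367926 (CD45-) and 26513530 (CD45+) in batch 1, and 31778475 and 28506906 in batch 2. Kept CD45- cells had a median of 255990 reads and 3707 genes in batch 1 and 288818 reads and 3572 genes in batch 2; CD45+ cells had 225559 reads and 2448.5 genes, and 284092 reads and 2711 genes. The highest correlation of log levels between wells of the same plate was 0.693, so no well appeared to be deposited more than once within a plate. Wells of different plates were not compared in this way. Each plate counts as 1 sample, so differences between gates have no replicate check other than the repeat in the other batch.

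Ptprc (ENSMUSG00000026395) reads followed the sort, and Pdgfrb (ENSMUSG00000024620) reads were found in the CD45- gate and hardly at all in the CD45+ gate. At equal depth, 64.6% of CD45- cells in batch 1 (51 of 79, 95% interval 53 to 75%) and 42.7% in batch 2 (35 of 82, 31.8 to 54.1%) had a Pdgfrb read. Among CD45+ cells the share was 0 of 76 in batch 1, with an exact upper bound of 4.74%, and 3.85% in batch 2 (3 of 78, 0.80 to 10.8%). Ptprc reads were found in 68.4% (52 of 76, 56.7 to 78.6%) and 60.3% (47 of 78, 48.5 to 71.2%) of CD45+ cells, against 2.53% (2 of 79, 0.308 to 8.85%) and 4.88% (4 of 82, 1.34 to 12%) of CD45- cells. The summed level of Pdgfrb was 294 CPM (Poisson interval 288 to 301) and 220 CPM (214 to 225) in the CD45- plates, against 0.113 CPM (0.0234 to 0.331) and 5.73 CPM (4.88 to 6.68) in the CD45+ plates. A single CD45+ well of batch 2 held 151 of the plate's 164 Pdgfrb reads, wells left out included, and without that well, replicate 68, the level was 0.431 CPM. Ptprc stood at 469 CPM (460 to 477) and 303 CPM (296 to 309) in the CD45+ plates, and at 0.136 (0.0371 to 0.349) and 0.976 CPM (0.663 to 1.39) in the CD45- plates. With all reads, 86 of 93 and 82 of 93 CD45- cells and 3 of 92 and 6 of 90 CD45+ cells had a Pdgfrb read, and Ptprc reads were in 84 of 92 and 77 of 90 CD45+ cells. A share of cells with 1 read also counts reads carried between wells. In wells of at least 50000 reads, 23 of 79 and 20 of 82 CD45- cells held at least 100 CPM of Pdgfrb. So did 0 of 76 and 1 of 78 CD45+ cells.

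Genes of the extracellular matrix and of the contractile apparatus were higher in the CD45- gate in both batches. Of the 22 matrix genes, 19 were higher in CD45- by the 4-fold rule, 0 were higher in CD45+, and Col4a1, Col5a1 and Eln passed in neither direction. Col1a1 (ENSMUSG00000001506), a chain of type I collagen, stood at 4891 and 6028 CPM in the CD45- plates of batches 1 and 2 and at 234 and 1103 CPM in the CD45+ plates (log2 ratio -4.38 and -2.45). Col1a2, the other chain of that collagen, had log2 ratios of -4.56 and -3.09, Col3a1, the type III collagen chain, -3.82 and -2.45, and the matrix glycoprotein gene Sparc -3.23 and -2.77. Of the 11 contractile genes, 10 were higher in CD45-. Acta2 (ENSMUSG00000035783), the smooth muscle actin used to define myofibroblasts, stood at 2313 and 2263 CPM against 361 and 76.2 CPM (log2 ratio -2.68 and -4.87). The contractile genes Cald1 (-3.25 and -4.14), Myl9 (-3.32 and -5.03) and Tpm1 (-2.24 and -3.41) had log2 ratios of the same sign. Postn, a secreted matrix protein of injured tissue, stood at 133 and 286 CPM against 32.3 and 0.211 CPM. Of the 15 remodelling genes, 9 were higher in CD45-, among them the collagen chaperone gene Serpinh1 (log2 ratio -2.92 and -4.12) and the protease inhibitor genes Timp1 (-3.83 and -5.06) and Timp3 (-3.48 and -2.93). Timp2 passed in neither direction (0.16 and -0.72), and its mean turned to 0.20 with TMM factors. Single wells of the CD45+ plates moved some of these values. Without replicate 5 of batch 1, Col1a1 stood at 129 CPM (log2 ratio -5.23), Postn at 11 CPM, and the ratios of Col1a2 and Acta2 were -5.19 and -3.28; the ratios were -4.99 (Col3a1) and -3.96 (Myl9) without replicate 91, and -3.97 (Serpinh1) and -4.47 (Timp1) without replicate 82. In batch 2, the ratios without replicate 18 were -6.34 (Col1a1, 73.3 CPM), -5.37 (Col1a2), -7.05 (Col3a1), -4.25 (Sparc), -5.65 (Myl9), -5.50 (Serpinh1) and -8.30 (Timp1). Acta2 was at -5.56 without replicate 29 and Timp3 at -4.36 without replicate 8. Col5a1 (-5.11) and Col4a1 (-2.29) both passed without replicate 18, which made 21 of 22 matrix genes, and Col4a1 also passed without replicate 28 (-2.55). All 11 contractile genes were higher in CD45- without CD45+ replicate 5 of batch 1. The remodelling count was 11 without that well, 10 without CD45+ replicate 91 of batch 1 or replicate 18 of batch 2, and 8 without CD45- replicate 11 of batch 1. The Postn ratio of batch 1, -2.01, was at the limit, and its call was lost without replicate 93 of the CD45- plate (-1.77) and without many other single wells, which left 18 matrix genes.

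The median log2 ratio of the matrix list was -4.17 in batch 1 and -3.25 in batch 2, at percentile 0 of the matched random lists in both. The contractile list had medians of -4.20 and -5.57 (percentile 0 in both) and the remodelling list -2.81 and -3.27 (percentiles 0 and 0.01). In the CD45+ plate of batch 2, 1 well, replicate 18, held 93.6% of the Col1a1 reads; without it, the batch 2 medians were -6.35 (matrix) and -5.50 (remodelling). In batch 1, the medians were -4.92 (contractile) and -3.44 (remodelling) without CD45+ replicate 5 and -4.86 (matrix) without replicate 91, and in batch 2 the contractile median was -6.16 without replicate 68. Hemoglobin transcripts, the markers of red blood cells, differed along with these groups: Hbb-bs stood at 7082 and 1554 CPM in the CD45- plates and at 4.12 and 10.3 CPM in the CD45+ plates. Without replicate 43 of the CD45- plate of batch 1, Hbb-bs stood at 3733 CPM there, and without replicate 43 of the CD45+ plate at 1.78 CPM. Hbb-bs was at or above 100 CPM in 93 of 93 kept CD45- cells of batch 1 and 81 of 93 of batch 2. Its mean was 76030 CPM in an unnamed cluster of 13 CD45- cells of batch 1, with a median of 16352 reads, and 3350 CPM in all other kept cells. Whether hemoglobin reads were carried between wells or came from free RNA was not tested.

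The 12 genes chosen by size in the CD45- direction were Sfrp4, Col6a2, Igfbp6, Hbb-bs, Aspn, Ogn, Actg2, Hba-a2, Vcan, Dclk1, Hba-a1 and Dkk3. Sfrp4, a secreted Wnt-binding protein, stood at 320 and 233 CPM in the CD45- plates and at 0.0378 and 0.211 CPM in the CD45+ plates. Col6a2, a type VI collagen chain, stood at 203 and 340 CPM against 0.302 and 0.246 CPM, and Igfbp6, which binds insulin-like growth factors, at 323 and 219 CPM against 0.302 and 0.457 CPM. Ogn and Aspn, small leucine-rich proteoglycans, had log2 ratios of -7.03 and -8.11, and of -7.09 and -7.68. Vcan, the large proteoglycan versican, had ratios of -6.66 and -6.73, Actg2, an actin of visceral smooth muscle, -7.61 and -6.94, Dclk1, a kinase, -6.62 and -6.80, and Dkk3 -6.51 and -8.01. The hemoglobin genes had ratios of -10.44 and -7.10 (Hbb-bs), -10.32 and -6.89 (Hba-a2), and -7.53 and -6.61 (Hba-a1). The marker lists of fibroblasts (7 of 8 genes higher in CD45-, medians -4.10 and -3.56, percentiles 0 and 0.02), smooth muscle (4 of 6, -6.00 and -6.30, percentile 0 in both) and pericytes (4 of 7, -2.91 and -2.71, percentiles 2.87 and 2.97) were on the same side. Of the mesangial markers, 1 of 5, Serpine2, was higher in CD45- (medians -0.99 and -4.43, percentiles 35.4 and 2.11). Without the CD45- well with most of its reads, Sfrp4 stood at 61.6 CPM in batch 1 (replicate 35) and 153 CPM in batch 2 (replicate 66), and the batch 1 ratios were -6.65 (Actg2, replicate 83) and -6.21 (Ogn, replicate 15). Without replicate 43 of that plate they were -9.51 (Hbb-bs), -9.46 (Hba-a2) and -6.69 (Hba-a1). Without replicates 43 and 5 of the CD45+ plate of batch 1, respectively, Hbb-bs was at -11.32 and Dkk3 at -7.30. The fibroblast medians were -4.87 without CD45+ replicate 91 of batch 1 and -6.71 without replicate 18 of batch 2, and the smooth muscle median of batch 1 was -5.38 without CD45- replicate 83. Of the smooth muscle markers, 5 passed without CD45+ replicate 5 of batch 1, and of the pericyte markers 5 without replicate 20; 6 fibroblast markers passed where the Postn call was lost. The pericyte medians were -3.81 and -4.11 without CD45+ replicates 20 and 86 of batch 1, and -4.20 without replicate 68 or 69 of batch 2. The mesangial median of batch 2 was -2.97 without CD45- replicate 68, and a different gene beside Serpine2 passed without CD45+ replicate 87 and without replicate 91 of batch 1.

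CD45+ cells held transcripts of antigen-presenting macrophages. All 7 antigen presentation genes were higher in CD45+: Cd74, the invariant chain that accompanies MHC class II, stood at 16008 and 33146 CPM against 170 and 627 CPM in CD45- (log2 ratio 6.55 and 5.72), and the class II gene H2-Aa had ratios of 7.44 and 6.56, H2-Ab1 of 6.18 and 5.49 and H2-Eb1 of 6.17 and 5.55. Of 13 chemokines and receptors, 9 were higher in CD45+, among them Ccl4 (8.76 and 7.56), Ccl3 (10.33 and 7.65), Cxcl2 (5.38 and 6.72) and Ccl7 (6.50 and 3.67), which attract monocytes or neutrophils. Cxcl12, a chemokine made by stromal cells, was the 1 member higher in CD45-, at 216 and 562 CPM against 1.4 and 9.7 CPM. The complement genes split: C1qa (6.70 and 5.87), C1qb (6.83 and 5.92), C1qc (6.75 and 5.61) and C4b were higher in CD45+, while C1s1 (-3.23 and -4.06) was among those higher in CD45-. The list medians were 6.17 and 5.55 for antigen presentation and 6.12 and 4.34 for chemokines and receptors, all at percentile 100, and 5.15 and 0.38 for the 8 measured complement genes, at percentiles 99.99 and 91.5. Some of the CD45- reads of these genes lay in few wells. Without the CD45- well with most of the gene's reads, the batch 1 ratios were 7.87 (Cxcl2, replicate 18), 7.31 (Ccl7, replicate 82), 7.82 (C1qa, replicate 10) and 9.40 (C1qc, replicate 66). In batch 2 they were 8.44 (Ccl4, replicate 82), 9.15 (Ccl3, replicate 51), 6.61 (C1qc, replicate 70) and, without replicate 27, 9.32 (Cxcl2) and 6.28 (Ccl7). In the CD45+ plates, Cxcl12 stood at 2.31 CPM in batch 2 without replicate 16, and the ratios of C1s1 were -5.47 without replicate 71 of batch 1 and -6.48 without replicate 18 of batch 2. The C4b call was lost without CD45+ replicate 71 of batch 2 (1.94), as was that of 1 antigen presentation gene, lost also without replicate 90 of batch 1. A further chemokine gene was higher in CD45- without CD45+ replicate 87 of batch 1. The chemokine median of batch 2 was 5.37 without CD45- replicate 27. The complement medians were 3.08 and 4.56 without CD45+ replicates 39 and 95 of batch 1, and 1.05 without CD45- replicate 34 of batch 2.

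The 12 genes chosen by size in the CD45+ direction were Fyb, Aif1, Fcgr1, Rgs1, Cyp4f18, Il1b, Ccl12, Ccl3, Mpeg1, Scimp, Cd300c2 and Ccl4. Fyb, an adaptor of immune receptor signalling, stood at 740 and 848 CPM against 0.204 and 1.04 CPM. Aif1, which encodes the macrophage protein IBA1, stood at 3407 and 2916 CPM against 8.14 and 3.15 CPM, and the inflammatory cytokine gene Il1b at 1102 and 1645 CPM against 0.511 and 6.27 CPM. Fcgr1, a high-affinity receptor for antibodies, had log2 ratios of 7.92 and 8.14, Mpeg1, a pore-forming protein of macrophages, 7.63 and 7.69, and the chemokine gene Ccl12 8.62 and 7.71. The ratios of Rgs1 were 8.08 and 7.91, of Cyp4f18 7.91 and 7.86, of Scimp 7.63 and 8.51, and of Cd300c2 7.81 and 7.57. The leukocyte markers (8 of 8 genes, medians 8.28 and 5.77) and macrophage markers (7 of 7, 6.70 and 5.87) were higher in CD45+, at percentile 100 in both batches. Without the CD45- well with most of the gene's reads, Aif1 stood at 1.58 CPM in the CD45- plate of batch 1 (replicate 5) and Il1b at 1.22 CPM in that of batch 2 (replicate 43). Without CD45- replicate 51 of batch 2, the ratio of Ccl12 was 8.89 and the median of the leukocyte markers 6.61.

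Several lists had few members on either side. Of 11 TGF-beta signalling genes, 4 were higher in CD45-, among them Ctgf, a matrix-associated growth factor target of this pathway (-5.45 and -5.46), and 7 passed in neither direction, among them the receptor genes Tgfbr1 (0.50 and 1.46) and Tgfbr2 (-2.12 and -1.20) and the secreted protein gene Tgfbi (2.84 and 1.47). The list medians were -1.63 and -2.57, at percentiles 7.44 and 1.14. Of 6 measured PDGF and hedgehog genes, Pdgfrb, Pdgfra (-2.70 and -5.27) and Gli2 were higher in CD45-, and the ligand genes Pdgfa (-0.08 and -2.09) and Pdgfc (4.57 and -3.70) passed in neither direction; the medians were -1.39 and -3.03, at percentiles 26.9 and 5.09. Each Pdgfc value rested on 1 well, which held 605 of 622 reads in the CD45+ plate of batch 1 and 423 of 426 in the CD45- plate of batch 2; without these wells, replicates 53 and 24, its ratios were 0.67 and 0.01. None of the 9 interferon response genes passed, with medians of 0.33 and -0.75 (percentiles 91.9 and 28.5), whose mean turned to 0.27 with TMM factors; Bst2 had ratios of 0.83 and 0.60, Ifit3 -1.24 and -1.96, Irf7 1.97 and -0.25, and Isg15 0.33 and -0.75. Of 14 dissociation and stress genes, 4 were higher in CD45+, including Zfp36 (2.67 and 2.45) and Btg2 (2.96 and 2.18), and the heat shock gene Hspa1a was higher in CD45-. The early response genes Fos (1.51 and 2.07) and Jun (1.30 and 0.77) passed in neither direction, and the list medians were 1.97 and 1.67 (percentiles 99.98 and 100). Of 7 measured fibrocyte-associated genes, 3 were higher in CD45+, the chemokine receptor gene Ccr2 (7.49 and 4.90) and the integrin genes Itgam and Itgb2. Lgals3 (1.94 and 2.05), Lsp1 (1.28 and 1.25) and Cd34 (-3.05 and -1.78) passed in neither direction, with list medians of 1.94 and 2.05 (percentiles 99.75 and 99.8). Single wells decided several of these calls. Gli2 lost its call without CD45- replicate 47 of batch 1 (-1.50) or of batch 2 (-0.12), and Hspa1a without CD45- replicate 27 of batch 2 (-0.89). Lgals3 passed without CD45- replicate 46 (3.24) or 24 (2.04) of batch 1, Cd34 without CD45+ replicate 44 (-2.09), 24 (-2.05), 8 (-2.03) or 28 (-2.02) of batch 2, and among the interferon response genes Ifit1 was higher in CD45- without CD45+ replicate 67 of batch 1 (-2.67) and another gene without replicate 87. The number of TGF-beta genes higher in CD45- was 3 without CD45- replicate 18 or 48 of batch 1 and 5 without CD45+ replicate 35 or 82 of batch 1. The number of stress genes higher in CD45+ was 5 without CD45- replicate 13, 48, 57, 61 or 68 of batch 2. The ratio of Ctgf in batch 2 was -6.99 without CD45+ replicate 18, that of Pdgfra in batch 1 -4.89 without CD45+ replicate 91, and that of Ccr2 in batch 2 6.64 without CD45- replicate 51. The interferon median of batch 2 was 0.24 without CD45- replicate 49, and that of batch 1 was -0.13, -0.09 and -0.01 without CD45+ replicates 87, 12 and 85. The PDGF and hedgehog medians of batch 1 were -0.52 without CD45- replicate 47, and -2.08 and -2.12 without CD45+ replicates 48 and 91; those of batch 2 were -2.15 without CD45- replicate 24 and -4.37 without CD45+ replicate 20. The fibrocyte-associated medians were 3.24 without CD45- replicate 46 of batch 1 and 2.67 without CD45- replicate 43 of batch 2.

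Over all 40594 genes, 558 were at least 4-fold higher in CD45+ and 1663 at least 4-fold higher in CD45- in both batches, and 507 differed 4-fold in opposite directions. Among 5199 genes that met the level and detection limits for naming, these counts were 368, 672 and 4. No test was run on these counts. CD45+ calls were 25.1% of all calls; TMM factors moved the median ratio of all genes by 0.32 in batch 1 and 0.48 in batch 2 and this share to 33.5%, and a pseudocount of 5 gave 367 and 681 calls, a share of 35%.

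**Figure D1:**
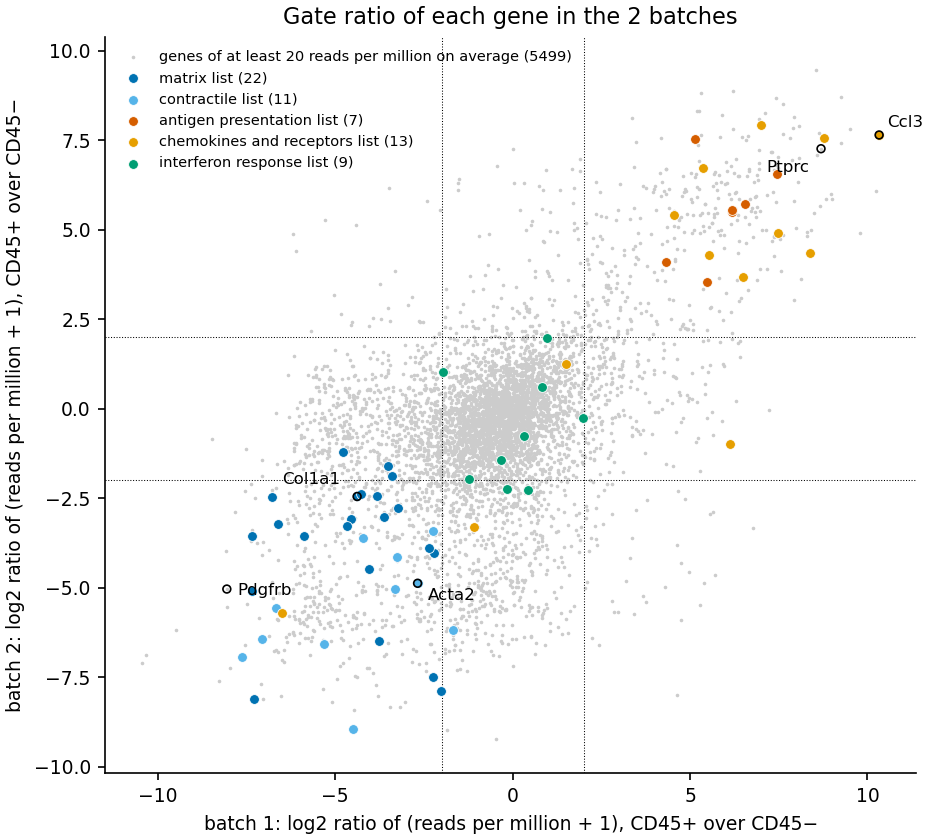
Each point is a gene of at least 20 CPM on average (5499 genes, grey), with its log2 ratio of CPM plus 1, CD45+ over CD45-, in batch 1 (horizontal) and batch 2 (vertical), 5 gene lists in colour and the 4-fold limits as dotted lines. Matrix and contractile genes lie in the lower left and antigen presentation genes in the upper right, with Pdgfrb at -8.05 and -5.04 (-7.27 in batch 2 without CD45+ replicate 68) and Ptprc at 8.69 and 7.26.

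**Figure D2:**
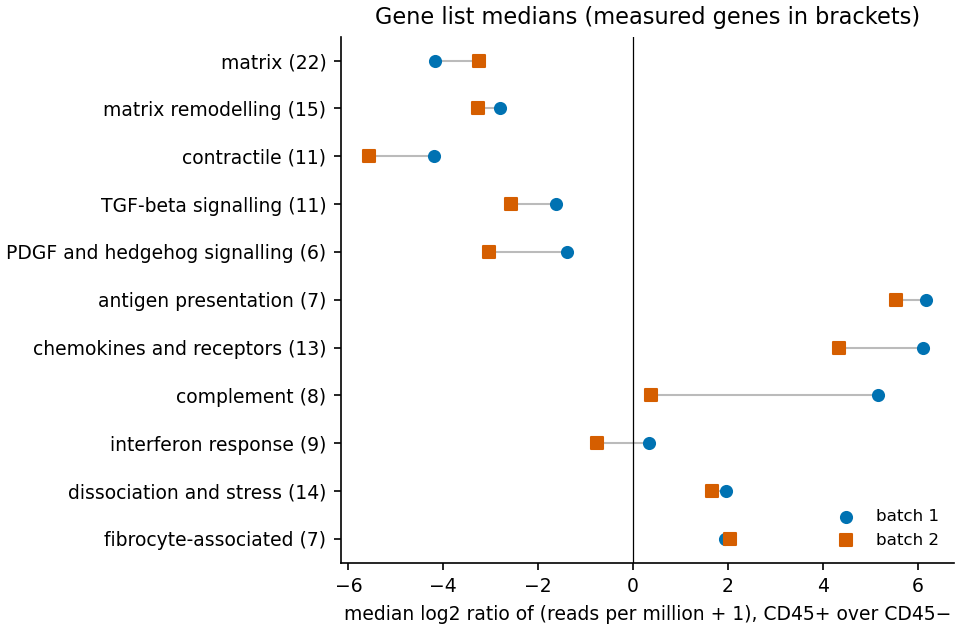
Median log2 ratio of CPM plus 1, CD45+ over CD45-, of each of the 11 gene lists in batch 1 (circles) and batch 2 (squares), with the number of measured genes in brackets. The interferon response list lies on different sides of 0 in the batches (0.33 and -0.75), and the complement list has the medians 5.15 and 0.38.

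Clustering of all 368 kept cells gave 9 clusters. The names rest on marker genes and the sort itself sets the shares below. Leukocyte-like clusters held 87% of CD45+ cells in batch 1 (80 of 92, 78.3 to 93.1%) and 93.3% in batch 2 (84 of 90, 86.1 to 97.5%), and 0 of 93 CD45- cells in each batch, with an exact upper bound of 3.89%. Among CD45+ wells of at least 50000 reads, the shares were 84.2% (64 of 76) and 92.3% (72 of 78). Mesenchymal-like clusters held 53.8% (50 of 93, 43.1 to 64.2%) and 55.9% (52 of 93, 45.2 to 66.2%) of CD45- cells, and 5 of 92 and 1 of 90 CD45+ cells. Of these CD45+ cells, the 1 of batch 2 (replicate 40) held 7738 CPM of Tyrobp, 9111 CPM of Lyz2 and 50.8 CPM of Col1a1, and replicate 8 of batch 1 held 19553 CPM of Tyrobp and 9.18 CPM of Col1a1, so these held leukocyte transcripts and few collagen reads. Endothelial-like cells, led by Tmem88, Egfl7, Gimap4, Cd34 and Gpihbp1, made up 29% (27 of 93, 20.1 to 39.4%) and 28% (26 of 93, 19.1 to 38.2%) of CD45- cells, and 0 of 92 and 2 of 90 CD45+ cells. Of endothelial-like cells in wells of at least 50000 reads, 5 of 26 in batch 1 and 0 of 26 in batch 2 held at least 100 CPM of Pdgfrb, against 18 of 49 and 20 of 48 mesenchymal-like cells, a threshold chosen after the data were seen. The shares of kept cells count wells under 50000 reads as cells, although these wells also served as a measure of carried reads. With the same clusters, 62% (49 of 79) and 58.5% (48 of 82) of CD45- wells of at least 50000 reads were mesenchymal-like. Of these wells, 5.06% (4 of 79) and 9.76% (8 of 82) were unnamed. Among all kept cells, the unnamed clusters held 16 and 15 CD45- cells and 7 and 3 CD45+ cells. Of these, 21 cells formed a cluster whose leading genes included Klk1, Car2, Sostdc1 and Krt18, in which Aqp2, the water channel of the collecting duct, was the only epithelial marker detected.

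The leukocyte-like and the mesenchymal-like class each consisted of clusters that followed the batch. A cluster of 90 leukocyte-like cells, led by C5ar1, Ighm, Pld4, Cd83 and H2-Ab1, held 9 cells of batch 1 and 81 of batch 2, and a cluster of 63, led by S100a8, Pim1, Ncf4, Apbb1ip and Ccl4, held 60 and 3. The mesenchymal-like clusters held 12 and 47 CD45- cells (led by Fmod, Ren1, Lum, Frzb and Col6a2) and 38 and 5 CD45- cells (led by Fhl2, Mgp, Loxl2, Tmem98 and Rarres2). Of the 476758 Ren1 reads in the CD45- plate of batch 2, 1 well held 407693, and reads carried between wells were not removed before clustering. Each plate is 1 library pool, so a cluster mostly of 1 batch is not told apart from that library. The clusters of 13, 11 and 7 cells had median depths of 16352, 14001 and 17645 reads, and of these the cluster of 11 was leukocyte-like; with finer clustering at resolution 2 the leukocyte-like shares of the CD45+ plates were 75% and 82.2%.

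**Figure D3:**
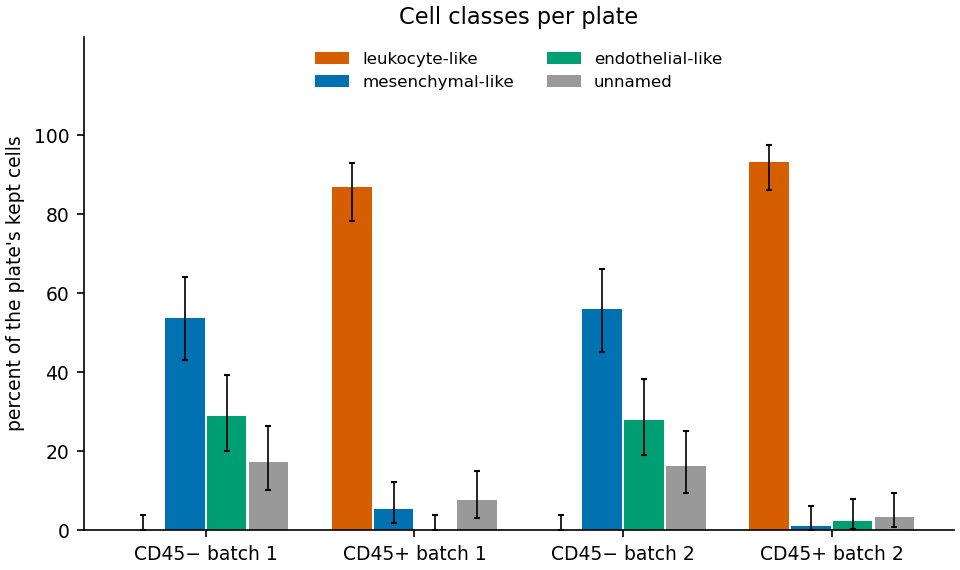
Percent of each plate's kept cells (vertical, 0 to 100) in leukocyte-like, mesenchymal-like, endothelial-like and unnamed clusters, with exact 95% binomial intervals as error bars. Leukocyte-like cells made up 87% and 93.3% of the CD45+ plates and 0% of the CD45- plates.

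Leukocyte-like cells of the CD45+ gate held few collagen reads per cell, with a median of 7 reads of Col1a1, Col1a2 and Col3a1 together in batch 1 and 21.5 in batch 2. Most of these cells lay in different clusters in the batches, so shares are given per batch. At equal depth, Col1a1 reads were found in 35.9% of them in batch 1 (23 of 64, 24.3 to 48.9%) and 68.1% in batch 2 (49 of 72, 56 to 78.6%). With all reads, replicate 18 of batch 2 held 29390 Col1a1 reads and the other wells of its plate a median of 7. Leukocyte-like wells of that plate also had a median of 7. In batch 1, the highest well held 2848 and leukocyte-like wells a median of 1. Whether reads carried from replicate 18 account for the higher Col1a1 share in batch 2 was not tested. In the endothelial-like and unnamed cells of the same plates, taken as background, the shares were 2 of 7 (3.67 to 71%) and 3 of 5 (14.7 to 94.7%), at median depths of 549760 and 346731 reads against 261106 and 298034 in the leukocyte-like cells; of those 7, 3 held 636 to 1279 CPM of Ptprc, so the background is not free of leukocyte reads. Col1a2 reads were found in 31.3% (20 of 64) and 55.6% (40 of 72) of leukocyte-like cells, Col3a1 reads in 56.3% (36 of 64) and 58.3% (42 of 72), Acta2 reads in 64.1% (41 of 64) and 25% (18 of 72), and Postn reads in 6.25% (4 of 64) and 2.78% (2 of 72). In those other cells, the shares were 2 of 7 and 1 of 5 for Col1a2, 0 of 7 and 1 of 5 for Col3a1, 2 of 7 and 0 of 5 for Acta2, and 0 of 7 and 0 of 5 for Postn. The intervals overlapped those of the leukocyte-like cells except for Col3a1 in batch 1 (43.3 to 68.6% against 0 to 41%). That difference rests on 7 wells. With all reads, Col3a1 was found in 7 of 7 of those other cells and 70 of 80 leukocyte-like cells of batch 1. These shares cannot decide whether the difference at equal depth holds, because the median depths were 549760 and 208626 reads.

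At a level of at least 100 CPM in wells of at least 50000 reads, chosen after the data were seen, Col1a1 was found in 3.13% of leukocyte-like cells in batch 1 (2 of 64, 0.381 to 10.8%) and 22.2% in batch 2 (16 of 72, 13.3 to 33.6%). How far reads carried from replicate 18 raised the share of batch 2 was not tested. Acta2 was found at that level in 15.6% (10 of 64, 7.76 to 26.9%) and 4.17% (3 of 72, 0.868 to 11.7%). Col1a1, Col1a2 and Col3a1 were all at or above it in 0 of 64 leukocyte-like cells in batch 1, with an exact upper bound of 5.6%, and in 7 of 72 in batch 2 (9.72%, 4.0 to 19%). Of those 7 wells, 6 held 72469 to 139987 reads, and the remaining well, replicate 18, held 1246070. By comparison, 49 of 49 and 43 of 48 mesenchymal-like cells of the CD45- gate held all of them at that level, although collagens are among the markers that name this class. So did 17 of 26 (65.4%, 44.3 to 82.8%) and 16 of 26 (61.5%, 40.6 to 79.8%) endothelial-like cells of the CD45- gate. The mesenchymal-like shares were 100% (92.7 to 100%) and 89.6% (77.3 to 96.5%), so their interval lay higher in batch 1 and overlapped in batch 2. This level was thus not particular to the mesenchymal-like class in those plates. Whether collagen reads carried between wells brought endothelial-like wells to it was not tested.

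The collagen reads of the CD45+ plates lay in few wells. In batch 1, leukocyte-like cells held 10.8% of the plate's reads of these collagens (1989 of 18356), and 4 of the 5 mesenchymal-like wells held all of Col1a1, Col1a2 and Col3a1 at or above 100 CPM. These 4 wells, singled out after their values were seen, held 0 Pdgfrb reads and between 2.37 and 12.7 CPM of Ptprc. In batch 2, leukocyte-like cells held 99.9% (65287 of 65373), and replicate 18 alone held 91.7%. That well held Col1a1 at 23586 CPM, Dcn, a collagen-binding proteoglycan, at 7867 CPM, and the leukocyte genes Tyrobp at 3531 CPM and Cd74 at 8325 CPM, with 0 Pdgfrb reads, 0.803 CPM of Acta2 and 0.803 CPM of Ptprc. When each batch was clustered alone, replicate 18 was mesenchymal-like and the leukocyte-like share of batch 2 was 7.35%, while that of batch 1 was 39.9%.

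**Figure D4:**
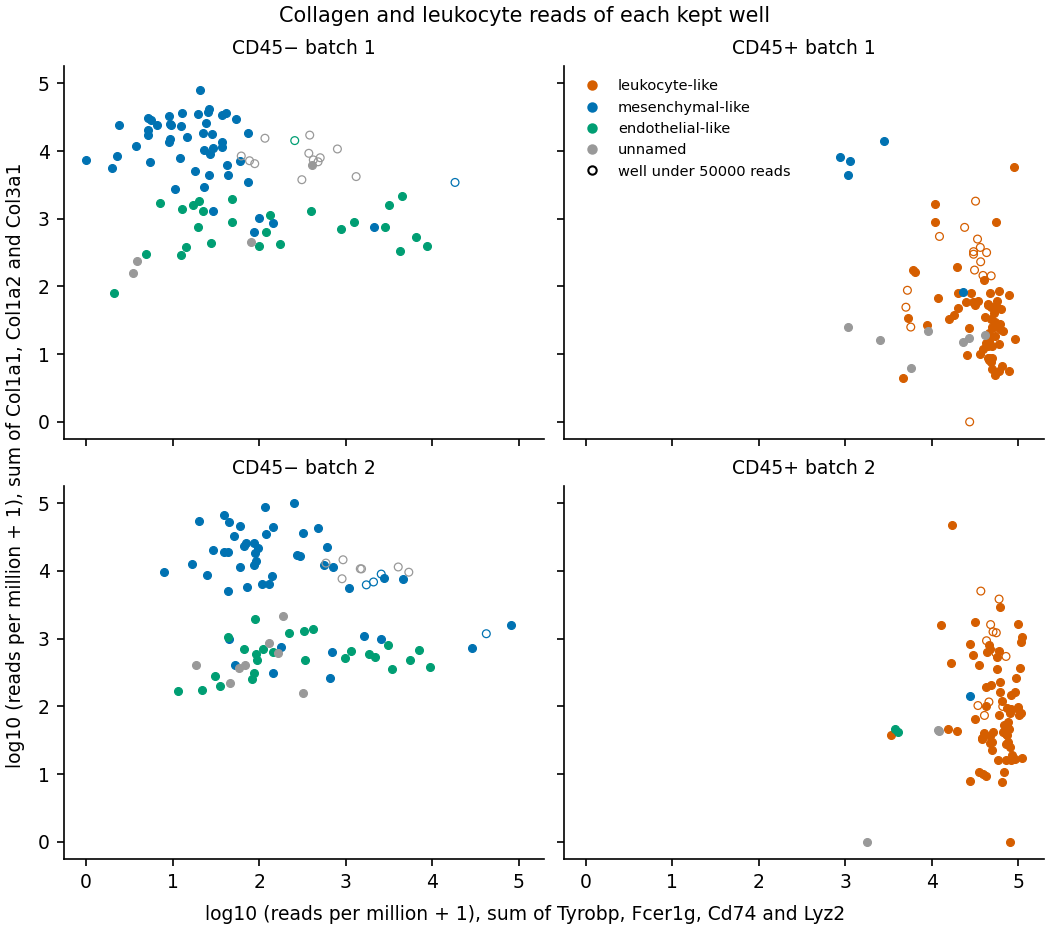
Each point is a kept well, with the log10 of CPM plus 1 summed over Tyrobp, Fcer1g, Cd74 and Lyz2 (horizontal) and over Col1a1, Col1a2 and Col3a1 (vertical), 1 panel per plate, coloured by class, with open circles for wells under 50000 reads. The mesenchymal-like wells of CD45+ batch 1 with collagen stand apart at the upper left of their panel, and in CD45+ batch 2 replicate 18, with 23586 CPM of Col1a1, stands alone at the top.

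Over the same genes, the repeat of the sort gave similar levels per gate and less similar gate ratios. Across 12882 genes of at least 1 CPM on average, which are not independent replicates, log levels of the CD45- plates had a Pearson correlation of 0.738 (Spearman 0.739) between batches and those of the CD45+ plates 0.646 (0.610). Levels of the gates within a batch had correlations of 0.539 (0.514) in batch 1 and 0.531 (0.533) in batch 2. The gate ratios of batches 1 and 2 had a correlation of 0.359 (Spearman 0.297), and of 0.560 (0.461) among 5499 genes of at least 20 CPM on average. Among the 5199 genes that met the limits for naming, it was 0.678 (0.605). In the CD45- gate, Ren1, which encodes the enzyme renin, stood at 412 CPM in batch 1 and 15007 CPM in batch 2, where 1 well held 407693 of 476758 reads; without the highest well of each plate, replicates 47 and 13, the levels were 46.3 and 2246 CPM. The other wells of batch 2 held a median of 98 Ren1 reads, 240 ppm of the highest well's reads, near the median of 265 ppm for genes mostly in 1 well of that plate. The interferon-induced chemokine gene Cxcl10 stood at 0 and 133 CPM there, and the interferon-induced gene Ifit1 at 7.33 and 148 CPM. In batch 2, replicate 49 alone held 3681 of 4223 Cxcl10 reads, and without it the levels were 17.6 CPM (Cxcl10) and 59.5 CPM (Ifit1). In the CD45+ gate, Mgp, an inhibitor of calcification, stood at 2867 and 317 CPM, Ifitm1, an interferon-induced membrane protein, at 796 and 5.41 CPM, and Dcn at 14.1 and 362 CPM, with replicate 18 holding 95.2% of the Dcn reads of batch 2. Without replicate 18, Dcn stood at 17.9 and Mgp at 60 CPM in batch 2; without replicate 27, Ifitm1 stood at 1.89 CPM, and without replicate 76 of batch 1, Dcn stood at 2.70 CPM there. The genes in this paragraph were chosen after their values were seen, and no test of a batch difference was run.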

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

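No test was run on these results, and none was planned, so the differences between batches below were not tested.

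Some list medians of the gate ratio, CD45+ over CD45-, lay on different sides of 0 in the batches. The interferon response list had medians of 0.33 in batch 1 and -0.75 in batch 2, a difference of -1.08. The proximal tubule markers (0 of 6 measured genes past the 4-fold rule, percentiles 91 and 31.4) had 0.57 and -1.34, a difference of -1.91. The distal tubule and collecting duct markers (0 of 6, percentiles 20.9 and 96.3) had -1.62 and 0.98, a difference of 2.60, and the podocyte markers (1 of 5 higher in CD45-, percentiles 66.7 and 88.9) -0.05 and 0.43, a difference of 0.48. The proliferating cell markers had -0.44 and 4.59, a difference of 5.02. Without 1 well, 4 of these lists lay on the same side of 0 in both batches: the interferon median was 0.24 in batch 2 without CD45- replicate 49, the distal tubule median 0.94 in batch 1 without CD45- replicate 46, the podocyte median -0.92 in batch 2 without CD45+ replicate 45, and the proliferating median 1.14 in batch 1 without CD45- replicate 82. The interferon median of batch 1 was -0.13, -0.09 and -0.01 without CD45+ replicates 87, 12 and 85, and the podocyte medians were 0 without CD45- replicate 92 of batch 1 and -0.04 without CD45+ replicate 71 of batch 2. The proliferating medians were -1.67 without CD45+ replicate 90 of batch 1 and 2.63 without CD45+ replicate 86 of batch 2. The distal tubule medians were -2.93 and -2.21 without CD45+ replicates 34 and 83 of batch 1 and 1.57 without CD45- replicate 8 of batch 2. The proximal tubule medians were 1.22 without CD45- replicate 7 of batch 1, and in batch 2 -0.63 and -0.36 without CD45- replicates 44 and 67 and -2.78 without CD45+ replicate 41. The podocyte gene higher in CD45- lost its call without CD45- replicate 1 of batch 1, Aqp2 was higher in CD45- without CD45+ replicate 34 of batch 1 (-3.79), and a different distal tubule gene was higher in CD45+ without CD45- replicate 12 of batch 2.

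Single genes differed in the same way. Isg15, an interferon-induced protein modifier, had log2 ratios of 0.33 and -0.75 (difference -1.08), Irf7, a transcription factor of the interferon response, 1.97 and -0.25 (-2.22), and Timp2 0.16 and -0.72 (-0.88). Isg15 was at 0.24 in batch 2 without CD45- replicate 49. Pdgfc had 4.57 and -3.70 (-8.27), each from 1 well, and 0.67 and 0.01 without CD45+ replicate 53 of batch 1 and CD45- replicate 24 of batch 2. Genes at least 4-fold different in opposite directions among those that met the limits for naming were Borcs8 (-2.53 and 2.42, difference 4.95), Itsn2 (-2.06 and 2.08, difference 4.14), Slc46a1, a folate transporter gene (2.41 and -2.44, difference -4.85), and Il1f6, an interleukin 1 family cytokine (-2.96 and 2.91, difference 5.87). In the CD45- plate of batch 1, 1 well held 4253 of 5781 Il1f6 reads, and without it (replicate 18) the ratio was -1.09; without CD45+ replicate 40 of batch 2 it was 1.88. The 4-fold difference in opposite directions was also lost for Itsn2 without CD45- replicate 51 of batch 1 (-1.61) or CD45+ replicate 93 of batch 2 (1.82), and for Slc46a1 without CD45+ replicate 47 of batch 1 (1.62). Without CD45+ replicate 18 of batch 2, Slc46a1 was at -6.22, and without CD45- replicate 63 of batch 1 at 3.77. Borcs8 was at -5.51 without CD45+ replicate 44 of batch 1 and at 3.04 without CD45- replicate 68 of batch 2.

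The 16 wells left out as too shallow held 123680 reads on genes, 54875 in batch 1 and 68805 in batch 2, which is above the limit of a count of 0.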

How the results depend on the processing

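No test was run, so no call could be lost by a p-value, and 4 settings were chosen after the data were seen: a threshold of 100 CPM in wells of at least 50000 reads, leaving out wells under 50000 reads, leaving out replicate 18 of CD45+ batch 2, and leaving out each well in turn. No paired analysis was possible because replicate numbers only name wells and match no samples between plates; by batch, gates were compared within each batch, and a fit of the 4 plate sums with the batch as a block was not run. Values below are list medians and gene ratios averaged over the batches unless 1 batch is named, and the cause was not tested where a value moved, except where a setting by its construction uses fewer genes, wells or batches. Of 543 values of named genes under planned settings, 472 stayed within the spread between batches, 65 moved and 6 turned sign. Of 88 list medians, 73 stayed, 12 moved and 3 turned sign. Part of those that stayed was fixed in advance. A value of 1 batch alone lies within that spread by construction unless it turns sign. The minimum of 20 CPM leaves the ratio of a single gene unchanged. These counts therefore overstate how stable the values were. Of 68 named genes, 39 had a ratio moved by over 1.5 times without the well with most of its reads, 31 of them among the 53 that passed, and 2 of the 53 lost the call, Postn among them; without any 1 of 368 wells, 550 to 569 genes were higher in CD45+ and 1643 to 1726 in CD45-. Depth limits the shares of cells with a read, which differed between thinned and all reads as given below.

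Shares of cells with a read depended on depth and threshold. With all reads, Pdgfrb was found in 92.5% and 88.2% of CD45- cells and Ptprc in 12.9% of CD45- cells of batch 2 and 91.3% and 85.6% of CD45+ cells; Col1a1 was found in 71.3% and 95.2% of CD45+ leukocyte-like cells. With wells of at least 200 genes and 1000 reads, the same shares were 91.7% and 86.5%, 15.6%, 91.7% and 83.3%, and 71.3% and 95.6%. With at least 5 reads, Ptprc was found in 0% and 1.08% of CD45- and 56.5% and 41.1% of CD45+ cells, and Col1a1 in 20% of leukocyte-like cells of batch 1. At 100 CPM, Pdgfrb was found in 29.1% and 24.4% of CD45- cells, Ptprc in 0% and 0% of CD45- and 32.9% and 25.6% of CD45+ cells, and Col1a1 in 3.13% and 22.2% of leukocyte-like cells.

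The leukocyte-like share of CD45+ cells was 75% and 82.2% at resolution 2, 81.1% in batch 2 with 10 principal components, and 94.6% in batch 1 clustered alone. The mesenchymal-like share of CD45- batch 1 was 67.1% when wells under 50000 reads were left out before clustering. The leukocyte-like share of collagen reads was 9.94% and 99.2% at resolution 2, 99.2% in batch 2 with 10 components, 40.3% and 99.8% with at least 1000 genes, 39.9% and 7.35% with each batch alone, 10.3% and 99.02% without wells under 50000 reads, and 98.4% in batch 2 without replicate 18.

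Counts of genes higher in CD45+ and in CD45- were 367 and 681 with a pseudocount of 5, 1725 and 3838 in batch 1 alone and 1518 and 4160 in batch 2 alone; a minimum of 20 CPM left 672 higher in CD45-. TMM factors kept all of the 558 CD45+ genes among 674 and gave 1336 CD45- genes. Averaging over cells gave list medians of -4.38 (matrix), -3.51 (remodelling), -1.07 (TGF-beta), 5.04 (antigen presentation) and 2.25 (fibrocyte-associated). TMM factors gave -2.57 (remodelling), 6.34 (antigen presentation), 2.30 (stress) and 2.48 (fibrocyte-associated), and turned the sign of the interferon list to 0.27, Isg15 to 0.27 and Timp2 to 0.20. A pseudocount of 5 gave -2.64 (remodelling). A minimum of 20 CPM gave -3.87 (PDGF and hedgehog) and 2.18 (stress) and turned the interferon list to 0.0432. In batch 1 alone, the interferon list (0.33), Isg15 (0.33) and Timp2 (0.16) were above 0, and in batch 2 alone Pdgfc (-3.70) and Irf7 (-0.25) were below 0. Without replicate 18, the matrix list was at -5.26 and the remodelling list at -4.15. The correlation of gate ratios was 0.560 over genes of at least 20 CPM on average.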

Other observations

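The tests of explanations in this part and the level of 100 CPM were chosen after the results were seen. Marker lists fixed before the data were examined described further leukocytes in the CD45+ gate. Of 5 monocyte markers, 4 were higher in CD45+ (medians 5.19 and 4.90, percentiles 99.9 and 99.96), including the receptor gene Ccr2; Ly6c2, a surface marker of inflammatory monocytes, stood at 43.5 and 157 CPM against 3.13 and 2.24 CPM, and Plac8 passed in neither direction (-0.76 and -1.43). Without CD45+ replicate 27 of batch 1 and replicate 71 of batch 2, which held most Ly6c2 reads, Ly6c2 stood at 22.2 and 48.7 CPM. The monocyte medians were 4.36 without CD45+ replicate 26 of batch 1 and 5.61 without CD45- replicate 51 of batch 2, and 3 markers were higher without CD45+ replicate 86 of batch 2. Of 6 neutrophil markers, 4 were higher in CD45+ (6.197 and 4.11, percentiles 100 and 99.9): S100a8, a calcium-binding protein of neutrophils and monocytes, stood at 926 and 277 CPM and was at or above 100 CPM in 29 of 92 and 11 of 90 cells. Those cells include 16 and 12 kept wells under 50000 reads, in which a few reads reach 100 CPM. The median S100a8 count per well was 9 reads in batch 1, and the part carried between wells was not tested. Without CD45+ replicate 85 of batch 2, S100a8 stood at 138 CPM there, and without replicate 46 the neutrophil median of batch 2 was 3.47. Among leukocyte-like cells in wells of at least 50000 reads, C1qa was at or above 100 CPM in 92.2% (59 of 64, 82.7 to 97.4%) and 95.8% (69 of 72, 88.3 to 99.1%), Csf1r, the receptor of a macrophage growth factor, in 32.8% (21 of 64) and 45.8% (33 of 72), Ccr2 in 28.1% (18 of 64) and 30.6% (22 of 72), and Ly6c2 in 1.56% (1 of 64) and 6.94% (5 of 72).

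Marker lists of lymphoid and dendritic cells had few members past the 4-fold rule. Of 6 T cell markers, Cd3g was higher in CD45+ in both batches (medians 0.91 and 4.35, percentiles 93.6 and 100), and Cd3d, a chain of the T cell receptor complex, stood at 0.0378 and 84.9 CPM with 0 and 3 cells at or above 100 CPM. Of 3 measured NK cell markers, 2 were higher in CD45+ (4.36 and 4.44, percentiles 99.8 and 99.7), of 2 measured B cell markers 1, Cd79b, at or above 100 CPM in 11 of 92 and 5 of 90 cells (4.63 and 3.67, percentiles 99.8 and 99.7), and of 4 measured dendritic markers Clec9a was higher in CD45+ and Zbtb46 in CD45- (0.51 and 3.64, percentiles 83.7 and 99.7). The counts of cells at 100 CPM for Cd3d and Cd79b include kept wells under 50000 reads. Of 7 proliferating cell markers, Mki67 and Nusap1 were higher in CD45+ (percentiles 51 and 99.99), and 1 well held 470 of 510 Mki67 reads in batch 2. Calls of Cd3g (0.48 without CD45+ replicate 65 of batch 1), Clec9a (0.06 without replicate 57 of batch 1, 0.22 without replicate 43 of batch 2) and Mki67 (1.77 without replicate 63 of batch 1, 1.18 without replicate 36 of batch 2) were lost without 1 well. So were those of Zbtb46 (-1.80 and -1.93 without CD45- replicates 62 and 91 of batch 1, -0.32 without CD45- replicate 49 of batch 2) and both NK cell markers (median 0.45 without CD45+ replicate 56 of batch 1). Nusap1 had ratios of 4.69 and 5.27, and of 3.74 and 2.63 without CD45+ replicates 85 and 86 of batches 1 and 2, and 1 more proliferating marker passed without CD45- replicate 86 of batch 1. Another was higher in CD45- without CD45+ replicate 36 of batch 2. Without CD45+ replicate 71 of batch 2, Cd3d stood at 3.43 CPM and the T cell median was 1.54; without CD45+ replicate 83 of batch 1 that median was 0.05, and without replicate 12 of batch 2 3.70. Without 1 CD45+ well, the batch 2 medians were 2.34 (NK cell, replicate 53), 2.69 (B cell, replicate 14) and 1.92 (dendritic, replicate 43). The endothelial markers passed in neither direction (0 of 7, -1.36 and -0.86, percentiles 9.21 and 21.3), and 4 of 4 measured erythroid markers were higher in CD45- (-9.90 and -6.75, percentile 0 in both). The erythroid median of batch 1 was -8.75 without CD45- replicate 43, and 1 endothelial marker was higher in CD45- without CD45+ replicate 86 of batch 1.

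Collagen reads in most leukocyte-like wells of the CD45+ plates may have been carried over between wells. Near-empty wells, those under 50000 reads, held a median of 4 reads of Col1a1, Col1a2 and Col3a1 in batch 1 and 12.5 in batch 2, against 7 and 21.5 in full leukocyte-like wells, so the ratio was 0.571 and 0.581 although the ratio of total reads was 0.0525 and 0.0538. The tables argue against transcripts of the leukocyte in the well as the whole source, since the collagen ratio was 14.6 times that of Tyrobp, Fcer1g, Cd74 and Lyz2 in the lower plate and 8.01 times from the lower quartile of near-empty wells. A first version of the test, replaced after its values were seen, compared endothelial-like and unnamed wells with leukocyte-like wells and gave ratios of 1.14 and 0.698 from 7 and 5 wells. It stays open whether a part of the reads in the wells above 100 CPM, such as replicate 52 of batch 1 with 546 Col1a1 reads and 0 reads of Col1a2 and Col3a1, was made in those cells.

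Almost no Pdgfrb reads were found in wells sorted as positive for PDGFRB and CD45. A level like that of the CD45- gate, missed for want of depth, is argued against: the highest upper bound of the share of CD45+ cells with a Pdgfrb read was 10.8%, below the lowest bound of 31.8% in the CD45- plates. Carried reads can raise the shares of the CD45- plates, which held most Pdgfrb reads. At 100 CPM in wells of at least 50000 reads, the lowest bound there was 15.6%. The highest upper bound in the CD45+ plates was 6.94% at that level. An exchange of the plates is argued against as well, since the lowest bound of the share with a Ptprc read was 48.5% in the CD45+ plates and the highest upper bound in the CD45- plates was 12%. A lower transcript level in cells that carry the protein, and antibody signal without the protein, were not tested and remain open.

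Replicate 18 of CD45+ batch 2 held collagen and leukocyte transcripts together. Tyrobp, Fcer1g, Cd74 and Lyz2 each had at least 3.57 times the reads of the highest near-empty well of the plate. Carry-over of leukocyte reads from other wells was not decided by this, because near-empty wells held under 50000 reads and replicate 18 held 1246070. In the full wells of the plate's endothelial-like and unnamed clusters, Cd74 stood at 652 to 6962 CPM and Fcer1g at 195 to 9647 CPM. Tyrobp stood at 34.3 to 1466 CPM and Lyz2 at 161 to 514 CPM there. Replicate 18 held 8325, 3538, 3531 and 1529 CPM of these genes, in that order. A well with more than 1 cell cannot be told apart from a single cell with both programmes: 97.4% of the other full wells of the plate had fewer genes than its 4342, but it also had the most reads of the plate. A single cell with both programmes remains possible and was not tested.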
